A study of Homo sapiens with 39 samples.

How the data were processed

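RNA was sequenced from cells labelled OVCAR3, an established line of high-grade serous ovarian carcinoma. It was collected after exposure to 30 µM or 45 µM atovaquone or to the vehicle, dimethyl sulfoxide (DMSO). Atovaquone is an antimalarial drug that inhibits mitochondrial complex III. Cultures were collected at 1, 8, 24 and 48 h, and untreated cultures at 24 h, which makes 13 groups of 3 libraries. The labels call the 3 replicates of a condition biological. They also place them in sequencing batches. Batch A holds 1 replicate and batch B 2 replicates of each treated and DMSO group of 1, 8 and 24 h, and batch C holds all libraries of 48 h. The titles of the untreated libraries name each batch once. RNA was collected in TRIzol and purified with an RNeasy kit, and a service company, Novogene, prepared and sequenced the libraries, per the labels' protocols. The RNA selection, the strandedness of the libraries and the read length are not given in the sources used here.

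The authors deposited 1 table of expected counts, the estimated numbers of reads that RSEM assigns to each gene, for 63140 genes identified by Ensembl number. STAR, RSEM and the genome build GRCh38 are named per the submitters' processing notes, without versions. The annotation release and the settings of both tools are not given in the sources used here. Expected counts share reads that map to several genes among them by estimation, so values of near-identical genes, such as the histone genes, HSPA1A and HSPA1B, or the mitochondrial genes with nuclear copies, are uncertain. Of the deposited values, 8.1% were not whole numbers, and all were rounded to whole numbers before testing. Each of the 39 columns was matched to a sample by its name, and 0 columns of per-sample values were left unused. Symbols came from a table of Ensembl genes that held 62541 of the identifiers and gave a symbol for 42291 of them. Coordinates came from a GENCODE annotation of GRCh38, whose release may differ from the one the authors used.

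Total counts per library ran from 15580526 to 40512449, with a median of 17600396. Batch A spanned 16128654 to 24508882, batch B 16020041 to 40512449 and batch C 15580526 to 19024241. Levels are given as CPM, counts scaled so that each library has the same total. Replicates of each group were compared gene by gene before use. The untreated libraries titled batch A replicate 1 and batch B replicate 1 differed at 0 genes and were counted as 1 library, which left 38 distinct libraries. This library correlated across genes with the 24 h DMSO libraries of batch B at r = 0.996 and 0.990 and with that of batch A at r = 0.768 (log2 CPM), and it was entered as batch B. The other distinct untreated library is titled batch C and labelled batch B, and it was also entered as batch B.

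Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr with a minimum count of 10, robust glmQLFit). The 29 distinct libraries of 1, 8 and 24 h entered 1 fit with a term for batch, so that all groups shared 1 estimate of the spread per gene, and 18336 genes were tested. The 9 libraries of 48 h entered a fit of their own, in which 16346 genes were tested. The biological coefficient of variation was 15.9% in the first fit and 7.2% in the second. Because batch C holds no other time, 48 h was never compared with the earlier times within a model. P-values were adjusted over the genes tested in each of 16 comparisons by the Benjamini-Hochberg method, with a threshold of 0.05. Unless said otherwise, an error is the standard error of a log2 fold change between 3 and 3 libraries, and an adjusted p is that of edgeR.

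Before the data were examined, 42 gene lists were fixed, covering stress responses, metabolism, respiratory complexes, the cell cycle, cell death, immune signalling, ribosomes, histones and markers of ovarian carcinoma and of other cell types. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with the correlation estimated from the libraries. Camera compares a list with all other genes tested. The fry test was run as well, which asks whether the genes of a list move one way on balance and does not compare them with other genes. List p-values were adjusted over the lists within a comparison. Beside members past the threshold over all genes tested, members were counted as adjusted over the list alone. Of 224 list calls with the preset correlation, 28 held with an estimated correlation and 196 did not, so the second p stands, after the word estimated, beside each list described as called.

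The rule for named genes was fixed at the same time. It takes, for each treatment comparison with at least 10 genes called, the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 1 whose treated libraries all lay above, or all below, the control libraries of the same batch. It adds the 2 members with the smallest adjusted p of every list past the threshold, and a fixed panel of 30 genes, called or not. The text leaves out some of the genes that this rule names. Genes named outside it are said to have been chosen after their values were seen.

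The test was tried on simulated counts drawn from the mean of each gene in each batch and the real library sizes. In these counts 200 genes were changed by known folds, and the libraries were drawn without the pairing of replicates described below. Each fold was the same in every treated library of every batch. The shares that follow therefore do not cover genes whose change differs between batches A and B. In the design of 45 µM against DMSO at 8 h, 29.9% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 83.3% of those changed 4-fold were recovered, and 6 of 115 calls were false. At 24 h these shares were 40.3%, 58.2% and 86.4%, with 6 of 129 calls false, and at 48 h 58.2%, 77.6% and 93.9%, with 12 of 165 calls false. No recovered gene had the wrong sign. In a test of the list step at 24 h, a list of genes raised at least 2-fold passed and 0 of 41 random lists passed. Genes were drawn independently of each other, so this does not test lists whose genes vary together, as those of real lists can.

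Replicate names are shared between groups, so pairing was checked from the correlation across genes of the deviations of same-named libraries from their group means. At 1, 8 and 24 h every pair of groups gave r between 0.899 and 0.989, and within batch B alone r lay between 0.494 and 0.666, so the names were taken to pair the libraries. At 48 h the correlations of the 30 µM and 45 µM libraries with each other were 0.263, 0.118 and 0.21. Those with DMSO ran from 0.061 to 0.262. Only the comparison of doses was taken as paired at 48 h, a choice that these overlapping values do not settle. The planned fits had no replicate block, and the fit with the block was an alternative.

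The alternatives set before the data were examined were median-of-ratios size factors, DESeq2 1.42.0 in place of edgeR, no filter on low counts, the replicate block, no batch term, batch B alone, only the compared groups in the fit, and each library left out in turn. Batch B alone with the block, other treatments of the repeated untreated library and the block in list tests were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.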

Results

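Gene expression was measured by RNA sequencing in cells labelled OVCAR3, a line of high-grade serous ovarian carcinoma. The treatment was atovaquone, an antimalarial drug that inhibits complex III of the mitochondrial respiratory chain. The title of the series links the drug to oxidative stress, to the pentose phosphate pathway, which supplies NADPH, and to immunogenic cell death, a form of cell death that alerts the immune system. Each group of DMSO, 30 µM and 45 µM atovaquone at 1, 8, 24 and 48 h had 3 libraries, and the untreated group of 24 h had 2 distinct libraries. Total counts lay between 15580526 and 40512449 per library.

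The batches differed more than the treatments did. The libraries of batch A and batch B correlated across genes with a median r of 0.756, against 0.983 among libraries of batch A, 0.986 among those of batch B and 0.944 between batches B and C (log2 CPM). The first principal component held 74.9% of the variance. WT1 and SOX17, transcription factors of ovarian carcinoma that were chosen here after their values were seen, averaged 0.0262 ± 0.0599 and 0.595 ± 0.349 CPM (SD, n = 9) in batch A. They averaged 50.3 ± 16.5 and 156 ± 49.8 (SD, n = 18) in batch B and 32.1 ± 18.4 and 67.7 ± 20.1 (SD, n = 9) in batch C. TGFBI, a matrix protein chosen in the same way, averaged 574 ± 105 in batch A, 0.0796 ± 0.0598 in batch B and 1.65 ± 0.41 in batch C. Each treated and DMSO group of 1, 8 and 24 h held 1 library of batch A and 2 of batch B, so that among these groups the difference did not follow the treatment, and batch was a term of the model. Both distinct untreated libraries were entered as batch B. RNA of another cell line or population may be in batch A, as described further below. The 3 libraries of a group of 1, 8 or 24 h may then not come from the same line. Fold changes are pooled over batches A and B unless said otherwise, and for some genes they differed between the batches.

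The vehicle alone was compared with no treatment at 24 h. No gene passed an adjusted p of 0.05 in edgeR (0 of 18336), 224 had an unadjusted p under 0.05, and DESeq2 called 2. Of the gene lists, cytosolic ribosomal proteins were lower in untreated cells by a median log2 of -0.05 (adjusted p = 0.000247, estimated 0.97), with 0 of 82 members past the threshold. With the replicate block, 5 lists passed in place of 1, and in batch B alone 4 passed, while 0 passed in any of these fits with an estimated correlation. The call of ribosomal proteins was then lost in batch B alone (adjusted p = 0.758). Because both distinct untreated libraries were entered as batch B, the comparison rests on batch B.

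Cultures in DMSO changed between 1 and 24 h, with 91 genes higher and 118 lower at 24 h. Of the immediate early genes, which respond within minutes to growth signals or handling, 20 of 27 fell and 26 did over the list alone (adjusted p = 9.9e-50, estimated 0.000945). FOSB, EGR3 and EGR2 fell by 5.09 ± 0.90, 5.00 ± 1.04 and 4.74 ± 0.80 on the log2 scale; they were chosen after their values were seen, since the rule names genes of treatment comparisons. STAT3 targets fell as a list, with 4 of 15 members past the threshold and 1 higher and 7 lower over the list alone (adjusted p = 5.28e-11, estimated 0.0221). Among NF-kB targets and cytokines 3 of 21 fell, and 13 over the list alone (adjusted p = 4.27e-13, estimated 0.233). Genes of G2 and mitosis moved the other way, with 3 of 26 higher and 22 over the list alone (median log2 0.39, adjusted p = 3.12e-21, estimated 0.194). The count of 209 genes was 103 in batch B alone, 445 with the replicate block and 404 by DESeq2. It fell to 64 without DMSO 1 h replicate A1, 127 without DMSO 1 h replicate B1, 84 without DMSO 24 h replicate A1, 97 without DMSO 24 h replicate B1 and 84 without DMSO 24 h replicate B2. Of the genes called in batch B alone, 29 of 32 higher (90.6%, against 49.1% of all genes) and 66 of 71 lower (93%, against 46.1%) had the same sign in batch A.

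At 1 h after the drug no gene passed the threshold at either dose. For 30 µM edgeR called 0 genes, with 137 at an unadjusted p under 0.05 and 2 called by DESeq2. For 45 µM it called 0, with 185 at an unadjusted p under 0.05 and 1 called by DESeq2, and 1 gene passed without 45 µM 1 h replicate A1. DDIT3, which encodes the stress transcription factor CHOP, had a log2 fold change of 0.64 (95% confidence interval 0.04 to 1.25) at 30 µM and of 0.98 (0.38 to 1.58) at 45 µM. CHAC1, an enzyme that degrades glutathione, had 0.79 (-0.08 to 1.66) and 1.14 (0.27 to 2.01), and each of these had an adjusted p of 1. The 34 ATF4 targets, which the integrated stress response induces, were higher as a list (adjusted p = 0.0216 and 0.0364, estimated 0.982 and 0.986), with 0 members past the threshold. The mitochondrially encoded mRNAs were lower as a list at both doses, by a median log2 of -0.11 and -0.12 (adjusted p = 0.00104 and 0.00106, estimated 0.982 and 0.986), and 0 and 2 of 13 were lower over the list alone. In batch B alone the lists of NF-kB targets (adjusted p = 0.00262 and 0.018, estimated 0.978 and 0.661) and immediate early genes (0.000159 and 0.00344, estimated 0.978 and 0.661) passed as well. Between the doses at 1 h edgeR called 0 genes, with 168 at an unadjusted p under 0.05 and 1 by DESeq2.

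At 8 h no gene passed the threshold at 30 µM and 152 did at 45 µM. At 30 µM edgeR called 0 genes, against 502 at an unadjusted p under 0.05 and 10 called by DESeq2. With the replicate block 3 genes passed, in batch B alone 6, and in batch B with the block 102. As a list, the targets of ATF4, the transcription factor of the integrated stress response, were nevertheless higher at 30 µM, with a median log2 of 0.54, 18 of 34 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 9.52e-38, estimated 0.0326). Several members rose less in batch A than in batch B. Log2 differences in A and B were 0.39 and 2.23 for CHAC1, 0.46 and 1.56 for TRIB3 and 0.12 and 0.89 for ASNS. They were -0.43 and 1.66 for DDIT4, while DDIT3 had 1.86 and 1.29. DDIT3 stood at 1.52 ± 0.31, SLC7A11, the cystine transporter, at 1.23 ± 0.27, and TXNIP, which binds thioredoxin and limits glucose uptake, at -2.21 ± 0.48, each with an adjusted p of 0.455. SLC7A11 passed with the block (adjusted p = 0.011) and DDIT3 in batch B alone (1.30, adjusted p = 0.0162). The targets of NRF2, the transcription factor that responds to oxidants, were higher as a list, with a median log2 of 0.06, 0 of 27 past the threshold and 1 over the list alone (adjusted p = 0.00768, estimated 0.634). SLC7A11 belongs to this list and to that of the ATF4 targets. Heat shock genes were lower as a list (adjusted p = 0.0173, estimated 0.634), a call that ended with the block (adjusted p = 0.101).

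At 45 µM and 8 h, 110 genes rose and 42 fell. INHBE, a subunit of activin E, rose 20.1-fold (log2 4.33 ± 0.61, adjusted p = 0.000719), and GDF15, a stress cytokine, by a log2 of 3.07 ± 0.53. CHAC1, located on chromosome 15 from 40952962 to 40956519 (ENSG00000128965), rose by 2.99 ± 0.45, the peptide hormone gene ADM2 by 2.87 ± 0.45 and the netrin receptor gene UNC5B by 2.74 ± 0.31. In batch A ADM2 averaged 0.134 CPM, and UNC5B stood at 0 CPM in DMSO and 0.181 at 45 µM, so that these values rest on batch B. ATF4 targets led the groups, since 21 of 34 rose and 32 did over the list alone (adjusted p = 1.55e-58, estimated 0.00346). They included DDIT3 (2.54 ± 0.32), SLC7A11 (2.11 ± 0.27), TRIB3, a pseudokinase (2.11 ± 0.35), SESN2, an inhibitor of mTORC1 (1.97 ± 0.34), and CEBPG (1.06 ± 0.13), and ATF4 itself rose by 0.83 ± 0.19. ASNS, which makes asparagine, and DDIT4, another inhibitor of mTORC1, stood at 1.53 ± 0.39 and 2.37 ± 0.64 without passing (adjusted p = 0.069 and 0.0987).

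Of 20 cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 8 rose, and 11 rose and 1 fell over the list alone, led by AARS1 (1.07 ± 0.16) and GARS1 (1.09 ± 0.17; list adjusted p = 4.61e-11, estimated 0.163). In serine and one-carbon metabolism 5 of 16 rose and 7 over the list alone, among them PSPH (1.06 ± 0.15) and MTHFD2 (1.01 ± 0.15; adjusted p = 5.82e-05, estimated 0.0692). Of the NRF2 targets 1 of 27 rose and 3 over the list alone (adjusted p = 0.0115, estimated 0.583). The 1 that rose was SLC7A11, which is also on the list of ATF4 targets. SRXN1 and OSGIN1, NRF2 targets that are not on that list, stood at 0.24 ± 0.11 and 0.58 ± 0.18 (adjusted p = 0.476 and 0.18). VEGFA, the angiogenic factor, rose by 1.56 ± 0.20, MYC by 1.02 ± 0.21, the cell death gene HRK by 1.55 ± 0.25, XBP1 by 0.80 ± 0.13, HERPUD1 by 0.79 ± 0.19 and GADD45A, a stress and DNA damage gene, by 0.97 ± 0.17. Heat shock genes went down, with 4 of 16 falling and 9 over the list alone, including the chaperone genes DNAJA1 (-0.56 ± 0.08), HSPA8 (-0.69 ± 0.15) and HSPA1A (-0.74 ± 0.17; adjusted p = 1.1e-09, estimated 0.111). HSPA1A has a near-identical copy, so its value is uncertain. G2 and mitosis genes were lower as a list with 0 of 26 past the threshold over all genes and 19 over the list alone (median log2 -0.33, adjusted p = 4.09e-16, estimated 0.253). TXNIP fell by 2.01 ± 0.47, the transcription factor gene SOX5, which stood at 0.0575 and 0 CPM in the batch A pair, by 1.34 ± 0.27, the kinase inhibitor gene CDKN2C by 0.88 ± 0.17, the mitochondrially encoded MT-ND2 by 0.75 ± 0.14 and FEN1, a nuclease of DNA replication, by 0.59 ± 0.14.

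The count of 152 genes at 45 µM and 8 h depended on single libraries and on the fit. It was 40 without DMSO 8 h replicate B1, 80 without DMSO 8 h replicate B2, 96, 61 and 45 without 45 µM 8 h replicates A1, B1 and B2. It was 258 in batch B alone, 352 with the replicate block and 326 by DESeq2, and 4 with no batch term. In the batch A pair, 162 of the 206 genes higher in batch B alone (78.6%, against 47.4% of all genes) and 45 of the 52 lower ones (86.5%, against 47%) had the same sign. Their median log2 differences were 0.26 and -0.27 in batch A, and 0.97 and -0.49 in batch B, where they were called. With the block ASNS passed (adjusted p = 0.00722), as did aryl hydrocarbon receptor targets as a list (0.0266, estimated 0.316, against 0.109 without it), while TXNIP did not (0.0507). In batch B alone DDIT4 passed (adjusted p = 0.00461), while MYC (0.214) and HSPA1A (0.0574) did not.

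**Figure D1:**
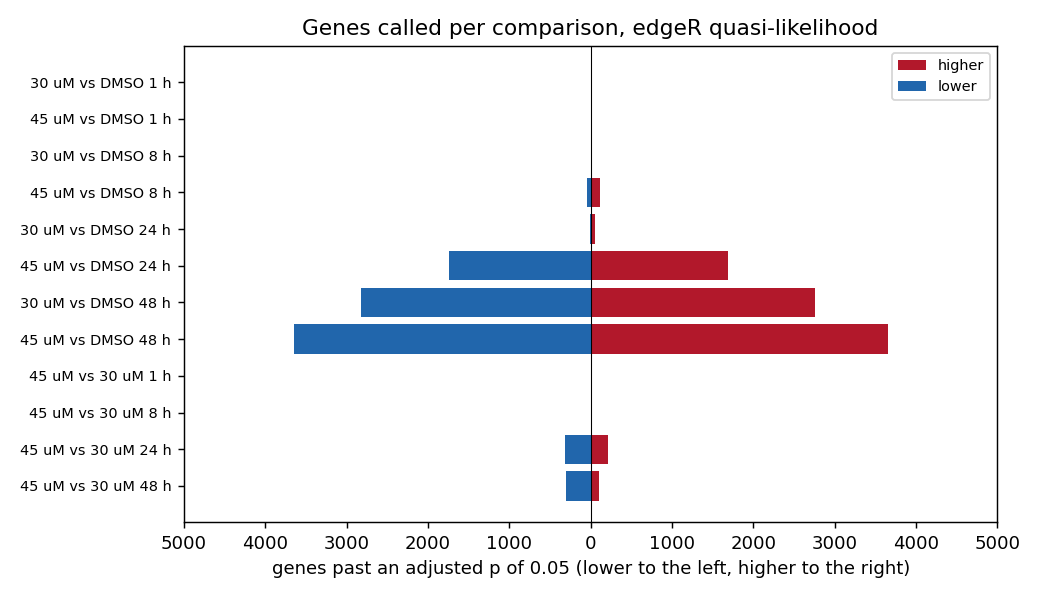
Number of genes past an adjusted p of 0.05 in edgeR for each comparison, with genes higher in the first-named group as bars to the right and genes lower as bars to the left. Against DMSO no gene passed at 1 h, and 3436 and 7293 did at 45 µM at 24 and 48 h.

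At 24 h the lower dose, 30 µM, raised 50 genes and lowered 11. Targets of NRF2 and of ATF4 were the 2 lists that passed with an estimated correlation as well. Of the NRF2 targets 5 of 27 rose and 17 over the list alone, including the sulfiredoxin gene SRXN1 (0.81 ± 0.11), OSGIN1 (1.28 ± 0.18), SLC7A11 (1.64 ± 0.27) and GCLC, the rate-limiting enzyme of glutathione synthesis (1.14 ± 0.19; adjusted p = 3.26e-24, estimated 0.0109). Of the ATF4 targets 7 of 34 rose and 31 over the list alone (adjusted p = 1.99e-40, estimated 0.0109), with INHBE, outside the list, at 2.69 ± 0.50, NUPR1 at 1.99 ± 0.29, DDIT3 at 1.89 ± 0.31, TRIB3 at 1.66 ± 0.34, CEBPG at 0.84 ± 0.13 and PCK2, outside the list, at 1.77 ± 0.33. Aminoacyl-tRNA synthetases rose in 3 of 20 cases and 10 over the list alone, among them SARS1 (0.73 ± 0.14; adjusted p = 1.75e-07, estimated 0.223). FTH1, the heavy chain of ferritin, rose by 0.57 ± 0.10, VEGFA by 1.09 ± 0.19, GADD45A by 0.92 ± 0.17, the transcription factor gene KLF4 by 0.81 ± 0.18, the sodium channel gene SCN4A by 2.10 ± 0.40 (0.0778 and 0.113 CPM in the batch A pair) and the glutathione transferase gene MGST1 by 0.30 ± 0.07.

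Among the falls at 30 µM and 24 h were the growth factor gene BMP7 (-0.93 ± 0.20), CDKN2C (-0.89 ± 0.17), GAS1 (-0.81 ± 0.15), DNAJA1 (-0.35 ± 0.08) and the mitotic genes KIF20A (-0.61 ± 0.13) and SPAG5 (-0.48 ± 0.10). BMP7 and GAS1 averaged 0.084 and 0.015 CPM in batch A, so that their values rest on batch B. G2 and mitosis genes were lower as a list, with 1 of 26 past the threshold over all genes and 20 over the list alone (median log2 -0.35, adjusted p = 5.72e-20, estimated 0.169). In the batch A pair, 119 of the 170 genes higher in batch B alone (70%, against 43.9% of all genes) and 27 of the 41 lower ones (65.9%, against 51%) had the same sign. Their median log2 differences were 0.17 and -0.08 in batch A, and 0.85 and -0.56 in batch B, where they were called. In batch B alone BMP7 (adjusted p = 0.0819), KIF20A (0.101), SPAG5 (0.077), DNAJA1 (0.0997), SLC7A11 (0.0819) and MGST1 (0.172) did not pass. The count of 61 genes was 211 in batch B alone, 222 with the replicate block, 210 by DESeq2 and 0 with no batch term. It was 11 and 31 without DMSO 24 h replicates B1 and B2 and 110, 18 and 30 without 30 µM 24 h replicates A1, B1 and B2. STAT3 targets passed as a list (adjusted p = 0.0436, estimated 0.469) but not with the block (0.0526).

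At 45 µM and 24 h, 1690 genes rose and 1746 fell, which was 18.7% of those tested. LAMP3, which encodes a lysosomal membrane protein, rose 20.9-fold (log2 4.39 ± 0.64), UNC5B by a log2 of 3.88 ± 0.31 (0.233 and 2.22 CPM in the batch A pair), INHBE by 3.50 ± 0.50, LCN2, an iron-binding secreted protein, by 3.42 ± 0.67 and GDF15 by 3.40 ± 0.53. Of the 34 ATF4 targets 29 rose and 1 fell, and 33 rose and 1 fell over the list alone (median log2 1.62, adjusted p = 3.58e-27, estimated 0.0344). DDIT3 reached 3.14 ± 0.32, ATF3 3.08 ± 0.70, NUPR1 2.83 ± 0.29, TRIB3 2.71 ± 0.35, DDIT4 2.67 ± 0.64, CHAC1 2.65 ± 0.43 and ASNS 2.49 ± 0.40. Some of these differed between batches A and B, with log2 differences of 0.73 and 4.02 for LCN2, 1.85 and 5.00 for LAMP3, 0.56 and 3.44 for DDIT4, 1.61 and 3.49 for ATF3 and 3.37 and 1.96 for ASNS. ATF4 mRNA stood at 0.45 ± 0.19 (adjusted p = 0.0996). Of the aminoacyl-tRNA synthetases 12 of 20 rose and 2 fell, and the same counts held over the list alone (adjusted p = 1.94e-05, estimated 0.248), with WARS1 at 1.46 ± 0.15 and SARS1 at 1.11 ± 0.14.

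Of the NRF2 targets 15 of 27 rose and 18 over the list alone, with SRXN1 at 1.45 ± 0.11, OSGIN1 at 1.95 ± 0.18, SLC7A11 at 1.91 ± 0.27, the heme oxygenase gene HMOX1 at 0.96 ± 0.30, the quinone reductase gene NQO1 at 0.82 ± 0.19 and FTH1 at 0.94 ± 0.10 (adjusted p = 4.2e-11, estimated 0.0793). Of 20 p53 targets 10 rose and 11 over the list alone, led by GADD45A (1.83 ± 0.17) and TNFRSF10B, a death receptor for TRAIL (1.49 ± 0.18; adjusted p = 1.72e-05, estimated 0.136). The kinase inhibitor gene CDKN1A rose by 1.21 ± 0.21. Of 17 genes of the BCL2 family and death receptors 5 rose, also over the list alone, including HRK (1.56 ± 0.24; adjusted p = 0.0023, estimated 0.248). Among immediate early genes 12 of 27 rose and 14 over the list alone, with KLF4 at 1.72 ± 0.18 and MYC at 1.10 ± 0.21 (adjusted p = 9.59e-06, estimated 0.248). Aryl hydrocarbon receptor targets rose in 5 of 9 cases, also over the list alone, with CYP1A1, a drug-metabolising enzyme, at 2.42 ± 0.46 (adjusted p = 0.00163, estimated 0.123). Of the genes of MHC class I presentation 4 of 17 rose and 5 over the list alone, including HLA-B (0.68 ± 0.17) and TAP2 (0.45 ± 0.12; adjusted p = 0.0448, estimated 0.496). Of the NF-kB targets and cytokines 3 of 21 rose, also over the list alone, including RELB (1.16 ± 0.24; adjusted p = 0.00478, estimated 0.54).

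Lists of cell cycle, sterol and heat shock genes fell at 45 µM and 24 h. All 26 G2 and mitosis genes fell, also over the list alone (median log2 -1.01, adjusted p = 9.75e-39, estimated 0.0344, or 0.0673 with the block), with KIF20A at -1.70 ± 0.14, DLGAP5 at -1.55 ± 0.13 and MKI67, a proliferation marker, at -1.31 ± 0.17. Of 32 genes of S phase 19 fell and 22 over the list alone, among them MCM4 (-0.80 ± 0.13) and FEN1 (-0.79 ± 0.14; adjusted p = 4.87e-10, estimated 0.257). Of 24 genes of cholesterol synthesis 20 fell and 23 over the list alone, with INSIG1 at -1.74 ± 0.20 and HMGCS1 at -1.46 ± 0.36 (adjusted p = 2.11e-16, estimated 0.0793). Of 14 genes of fatty acid synthesis 8 fell and 2 rose, and 9 and 2 over the list alone (adjusted p = 0.00128, estimated 0.0344), including ACSL3 (-0.52 ± 0.07). Heat shock genes fell in 12 of 16 cases, also over the list alone, with HSPH1 at -0.89 ± 0.11, DNAJA1 at -0.83 ± 0.08 and HSP90AA1 at -0.83 ± 0.12 (adjusted p = 7.31e-13, estimated 0.0344). CCDC146 fell by 2.67 ± 0.47 and SKIDA1 by 2.30 ± 0.33.

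Part of the transcripts of the respiratory chain fell at 45 µM and 24 h. Of the 13 mitochondrially encoded mRNAs 9 fell and 1 rose, and 11 and 1 over the list alone (median log2 -0.83, adjusted p = 7.06e-07, estimated 0.173), with MT-ND3 at -1.08 ± 0.14 and MT-CO3 at -0.89 ± 0.15. The mitochondrial rRNAs, named after their values were seen, rose in the same libraries, MT-RNR1 by 1.61 ± 0.37 and MT-RNR2 by 1.18 ± 0.33, and a difference in RNA selection was not told apart from an effect of the drug. Among nuclear subunits, 13 of 37 of complex I fell and 14 over the list alone (adjusted p = 2.18e-05, estimated 0.351), including NDUFB4 (-0.52 ± 0.08). Of complex III, the target of the drug, 4 of 9 fell, also over the list alone, including UQCRB (-0.45 ± 0.09; adjusted p = 0.00596, estimated 0.411). Of complex IV 5 of 12 fell and 1 rose, also over the list alone, with COX6B1 at -0.30 ± 0.06 and COX7A2L at 0.25 ± 0.06 (adjusted p = 0.0136, estimated 0.496). Of the ATP synthase 11 of 17 fell and 14 over the list alone, including ATP5MC3 (-0.68 ± 0.10; adjusted p = 5.65e-08, estimated 0.123). In glycolysis 6 of 22 fell, also over the list alone, including LDHA, which makes lactate (-0.71 ± 0.06; adjusted p = 0.00618, estimated 0.312). Replication-dependent histones fell in 8 of 40 cases, and 11 fell and 2 rose over the list alone, with H2BC12 at -0.76 ± 0.11 (adjusted p = 0.000108, estimated 0.152).

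Among genes tested in both fits, 1143 of the 1494 genes higher in batch B alone (76.5%, against 48% of all genes) and 1259 of the 1637 lower ones (76.9%, against 47.2%) had the same sign in the batch A pair. Their median log2 differences were 0.32 and -0.29 in batch A, and 0.69 and -0.55 in batch B, where they were called. TXNIP had a log2 difference of 1.51 in batch A and -0.76 in batch B, and did not pass (0.16 ± 0.45, adjusted p = 0.857). ATF4 mRNA passed with the block (adjusted p = 0.0165). Batch B alone called 3138 genes in all (1496 higher and 1642 lower) and batch B with the replicate block 5536, against 198 with no batch term and 1595 when only the compared groups entered the fit. Of the genes called at 45 µM and 8 h, 108 of the 110 higher and 38 of the 42 lower were called in the same direction at 24 h, where 10.1 and 4 would be shared by independent lists of these sizes. Both comparisons come from the same fit and share its estimate of the spread per gene, so these lists are not independent.

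**Figure D2:**
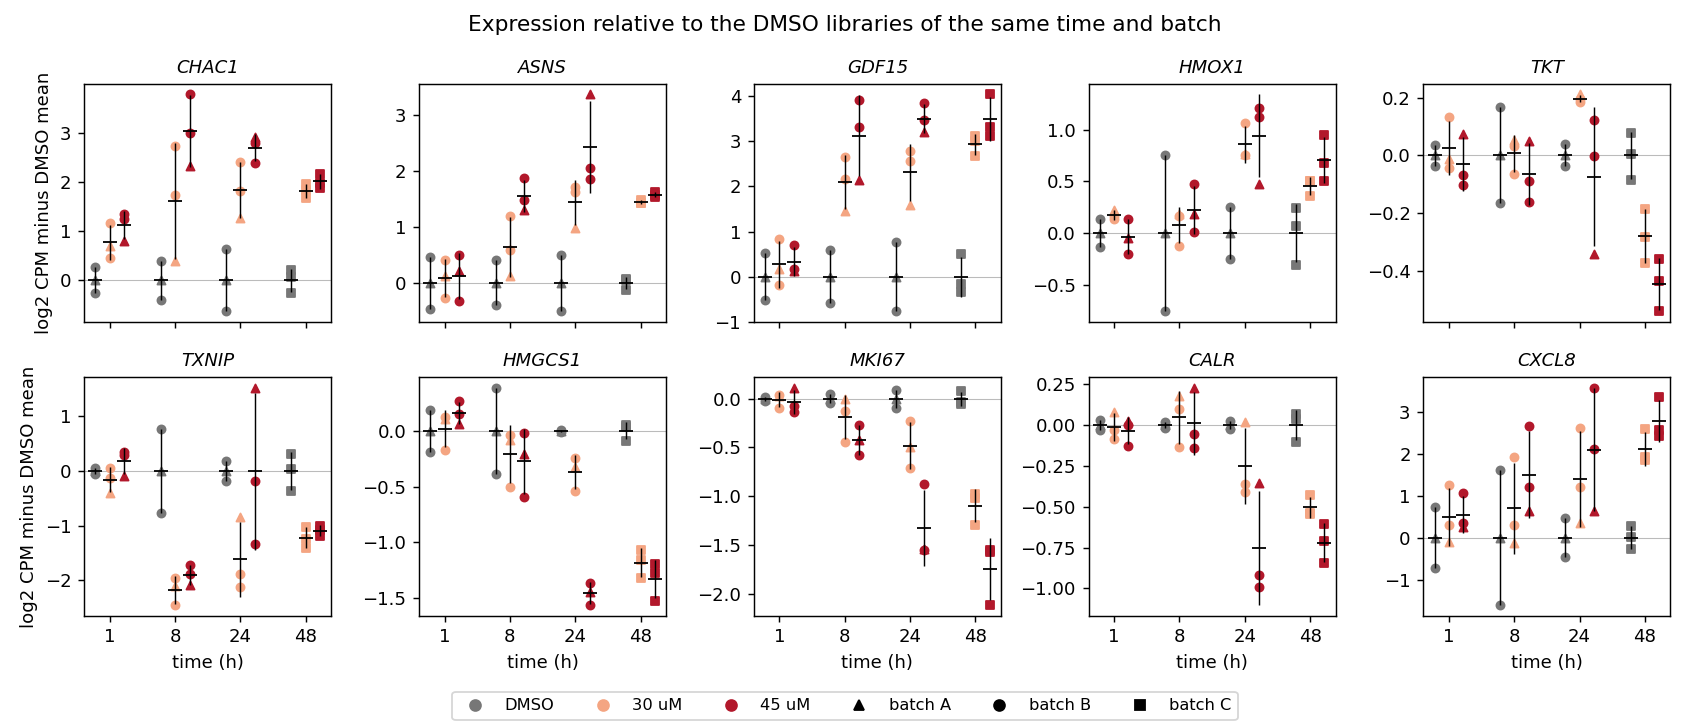
Log2 CPM of panel genes relative to the mean of the DMSO libraries of the same time and batch, by time in h, with 1 point per library, colour for treatment and shape for batch; error bars are the SD over libraries. The single DMSO library of batch A at each early time is its own reference and lies at 0, and the ATF4 targets lie above DMSO from 8 h on at 45 µM.

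At 48 h, in batch C, 30 µM raised 2759 genes and lowered 2825, and 45 µM raised 3652 and lowered 3641. These counts are not set against those of 24 h, because the coefficient of variation between replicates was 7.2% in batch C and 15.9% in the fit of the earlier times. The response of ATF4 targets was broad, since 33 of 34 ATF4 targets rose at each dose (median log2 1.05 and 1.28), and 33 rose and 1 fell over the list alone (adjusted p = 8.29e-77 and 3.05e-60, estimated 0.0131 and 0.0232). CHAC1 went from 21.6 ± 3.47 CPM (SD, n = 3) in DMSO to 76.0 ± 7.39 and 86.9 ± 9.04. ASNS rose by 1.45 ± 0.05 and 1.58 ± 0.05, GDF15 by 2.91 ± 0.37 and 3.51 ± 0.36, DDIT3 by 1.70 ± 0.14 and 2.08 ± 0.14, and ALDH1L2, a mitochondrial folate enzyme, by 2.16 ± 0.10 and 2.28 ± 0.09. Other large rises at 30 µM were MOV10L1 (3.11 ± 0.39), INHBE (2.92 ± 0.16) and NUPR1 (2.71 ± 0.30), and at 45 µM MOV10L1 (3.91 ± 0.37), C15orf48 (3.63 ± 0.56) and LAMP3 (3.48 ± 0.36). In serine and one-carbon metabolism 7 of 15 rose at each dose and 2 and 4 fell, also over the list alone (adjusted p = 9.24e-09 and 5.4e-05, estimated 0.0131 and 0.049). Of 20 aminoacyl-tRNA synthetases 11 rose and 5 fell at 30 µM and 12 rose and 6 fell at 45 µM, against 12 and 6 at both doses over the list alone (adjusted p = 1.44e-05 and 7.37e-05, estimated 0.0855 and 0.106).

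Inflammatory genes rose at 48 h. Of the 20 NF-kB targets and cytokines 19 rose at each dose, also over the list alone, with a median log2 of 1.42 and 1.94 (adjusted p = 4.16e-12 and 1.25e-12, estimated 0.173 and 0.154). IL6 rose by 2.48 ± 0.18 and 2.54 ± 0.18, TNF by 1.49 ± 0.20 and 2.02 ± 0.19, CXCL8, a neutrophil chemokine, by 2.14 ± 0.35 and 2.82 ± 0.35, CCL20 by 2.74 ± 0.40 and 3.54 ± 0.40, and CXCL10, a chemokine for T cells, by 1.19 ± 0.35 and 1.43 ± 0.34. Genes of MHC class I presentation rose in 9 of 16 cases at 30 µM, where 11 rose and 1 fell over the list alone. At 45 µM 10 rose and 1 fell, and 11 and 1 over the list alone, among them TAP1 (0.67 ± 0.11 and 0.88 ± 0.11) and HLA-E (0.52 ± 0.07 and 0.56 ± 0.07; adjusted p = 0.00165 and 0.00432, estimated 0.392 and 0.463). At 30 µM 19 of 29 type I interferon genes rose, and 19 rose and 2 fell over the list alone, including IFIT2 (1.00 ± 0.15) and STAT2 (0.41 ± 0.07; adjusted p = 0.000125, estimated 0.366). At 45 µM 8 rose and 6 fell, also over the list alone, and the list did not pass (adjusted p = 0.608).

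Mitotic, sterol and heat shock genes were lower at 48 h at both doses. G2 and mitosis genes fell in 24 and 25 of 26 cases, and in 25 and 26 over the list alone, with AURKA at -1.33 ± 0.07 and -2.01 ± 0.08 (adjusted p = 1.28e-45 and 4.67e-66, estimated 0.049 and 0.0329). The S phase list did not pass (adjusted p = 0.644 at 30 µM, where 7 rose and 3 fell, and 0.275 at 45 µM, where 6 rose and 9 fell). Genes of cholesterol synthesis fell in 22 and 24 of 24 cases, also over the list alone, with SQLE at -1.06 ± 0.07 and -1.11 ± 0.07 and HMGCS1 at -1.18 ± 0.08 and -1.33 ± 0.08 (adjusted p = 1.35e-24 and 9.94e-22, estimated 0.0131 and 0.0232). Heat shock genes fell in 13 and 15 of 16, also over the list alone, with HSPA8 at -0.77 ± 0.05 and -0.96 ± 0.05 (adjusted p = 1.05e-11 and 1.9e-12, estimated 0.049 and 0.0544). The sorting receptor gene SORCS1 fell by 2.10 ± 0.30 and 3.34 ± 0.34, GREM1, an inhibitor of BMP signalling, by 2.08 ± 0.31 and 3.27 ± 0.35, and the sialyltransferase gene ST8SIA4 by 2.38 ± 0.28 and 2.99 ± 0.30.

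Lists of nuclear subunits of the respiratory chain, glycolysis and ribosomal proteins were lower at 48 h. All 9 tested subunits of complex III fell at both doses, also over the list alone, with UQCRFS1 at -0.60 ± 0.06 and -0.59 ± 0.06 (adjusted p = 5.72e-06 and 7.36e-05, estimated 0.049 and 0.0568). Of the ATP synthase 16 of 17 fell at both doses, also over the list alone, with ATP5F1A at -0.64 ± 0.05 and -0.77 ± 0.05 (adjusted p = 7.53e-14 and 1.28e-12, estimated 0.049 and 0.0613). Of complex I 30 and 32 of 37 fell (adjusted p = 6.49e-11 and 7.98e-09, estimated 0.0904 and 0.118), and adjusted over the list alone 31 fell and 1 rose at 30 µM and 34 fell at 45 µM. Of complex IV 10 and 11 of 12 fell, also over the list alone (adjusted p = 5.36e-06 and 1.47e-05, estimated 0.124 and 0.13). The mitochondrially encoded mRNAs did not pass as a list (adjusted p = 0.271 and 0.0598). Of these 13, MT-ND2, MT-ATP6, MT-CO3 and MT-ATP8 were lower at both doses and 1 was higher at each, MT-CO2 (0.51 ± 0.16) at 30 µM and MT-ND1 (0.47 ± 0.11) at 45 µM, all named after their values were seen. Cytosolic ribosomal proteins fell in 50 and 44 of 82 cases, with 1 and 2 rising, and in 54 and 45 over the list alone (median log2 -0.18 and -0.15, adjusted p = 1.78e-08 and 0.000155, estimated 0.373 and 0.544). In glycolysis 11 and 12 of 21 fell and 2 rose, and 12 and 13 fell and 2 rose over the list alone (adjusted p = 5.36e-06 and 2.07e-06, estimated 0.0855 and 0.078), with LDHA falling by 0.86 ± 0.05 and 1.10 ± 0.05 and GAPDH by 0.43 ± 0.04 and 0.62 ± 0.04. Of the ovarian carcinoma markers 8 and 9 of 18 fell and 4 rose, and adjusted over the list alone 8 fell and 5 rose at 30 µM and 10 fell and 4 rose at 45 µM, with the keratin gene KRT8 at -0.74 ± 0.05 and -1.05 ± 0.05 (adjusted p = 0.000526 and 0.00011, estimated 0.108 and 0.0999).

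Lists of fibroblast, leukocyte and endothelial markers did not pass in any comparison of a dose with DMSO; at 45 µM and 48 h their adjusted p were 0.946, 0.39 and 0.608. At 48 h, 1228 of the 1646 genes higher at 45 µM and 24 h that were tested at both times were again higher, and 1344 of the 1704 lower were again lower, where independent lists would share 370 and 384.5; 17 and 6 went the opposite way.

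**Figure D3:**
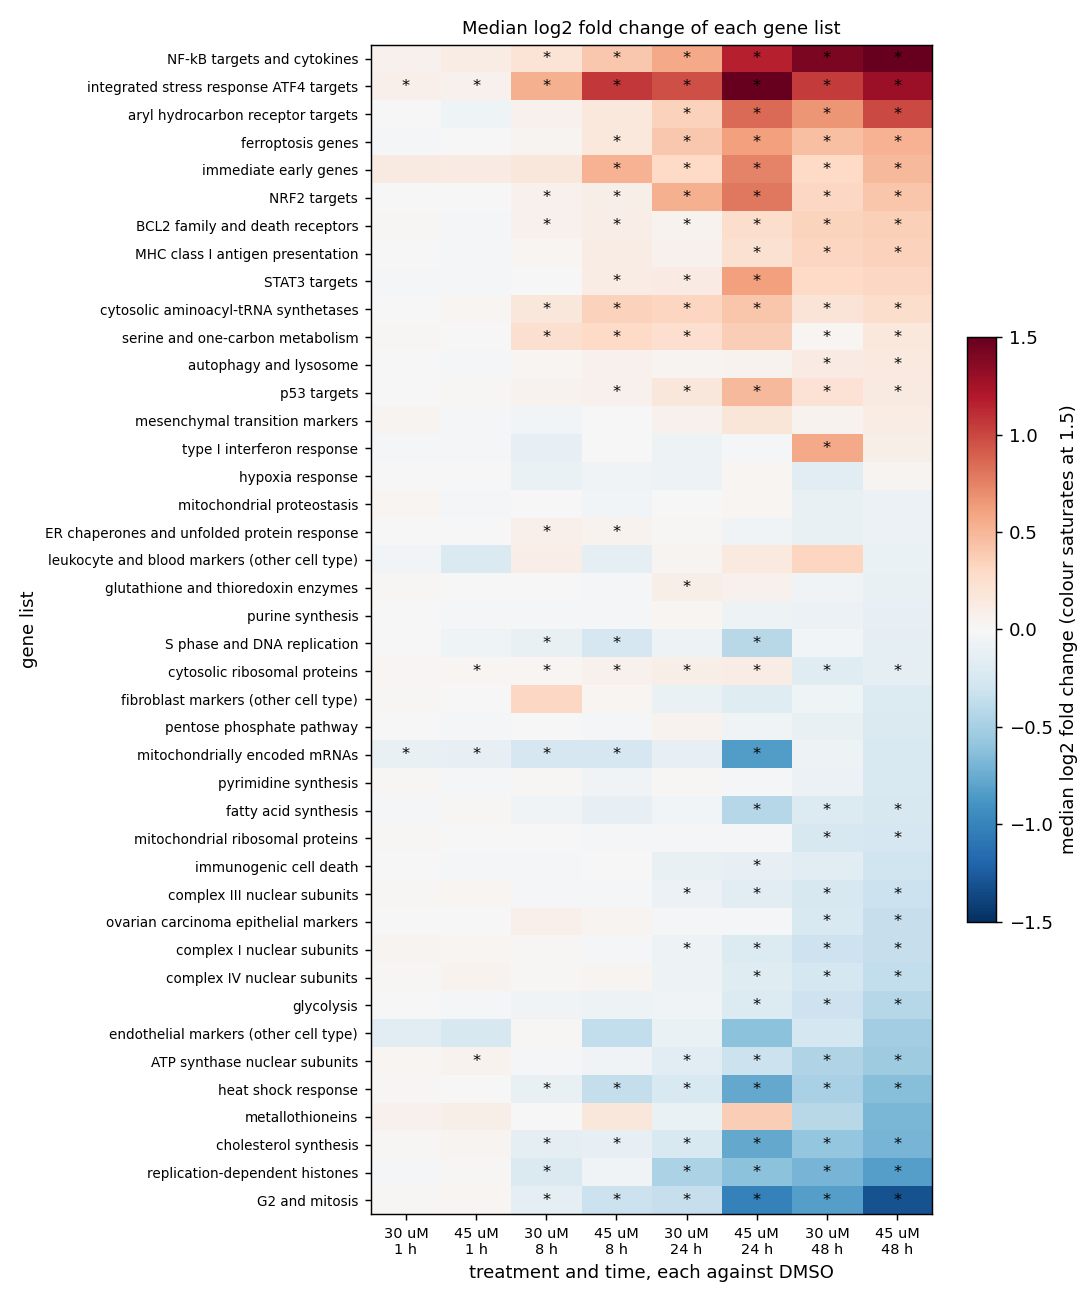
Median log2 fold change against DMSO of each gene list (vertical axis) in each treatment and time (horizontal axis), shown by colour, with marks on lists past an adjusted p of 0.05 in camera with a preset correlation. ATF4 targets had medians of 1.62 at 45 µM and 24 h and 1.28 at 45 µM and 48 h, and G2 and mitosis genes of -1.01 and -1.30.

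The difference between the doses was tested directly. At 8 h edgeR called 0 genes (557 at an unadjusted p under 0.05, and 1 by DESeq2), and 62 passed in batch B with the block. ATF4 targets were higher at 45 µM as a list, with a median log2 of 0.61 and 14 of 34 past the threshold adjusted over the list alone (adjusted p = 1.78e-34, estimated 0.0449). At 24 h 218 genes were higher and 312 lower at 45 µM than at 30 µM. G2 and mitosis genes were lower in 23 of 26 cases and in 26 over the list alone (median log2 -0.66, adjusted p = 3.89e-43, estimated 0.0152), with KIF20A at -1.09 ± 0.14. Heat shock genes were lower in 8 of 16 cases and 12 over the list alone (adjusted p = 1.07e-15, estimated 0.0144). Of cholesterol synthesis 9 of 24 were lower and 21 over the list alone, with INSIG1 at -1.33 ± 0.20 (adjusted p = 2.81e-19, estimated 0.0643). Of the mitochondrially encoded mRNAs 8 of 13 were lower and 1 higher, and 10 and 1 over the list alone, with MT-CO2 at -1.24 ± 0.23 (adjusted p = 1.94e-09, estimated 0.164, or 0.0369 with the block). Of the genes of immunogenic cell death 4 of 23 were lower and 7 over the list alone, among them HMGB1 (-0.47 ± 0.07; adjusted p = 0.000643, estimated 0.0144). Fatty acid synthesis had 2 of 14 lower and 8 over the list alone (adjusted p = 9.99e-07, estimated 0.00349). SRXN1 was higher by 0.64 ± 0.11, LAMP3 by 2.29 ± 0.55, TXNIP by 1.81 ± 0.46, the mitochondrial rRNA MT-RNR1 by 1.74 ± 0.37 and TGM1, a transglutaminase gene, by 1.70 ± 0.37. SKIDA1 was lower, at -1.76 ± 0.33. The count of 530 was 209 in batch B alone, 1108 with the block and 964 by DESeq2, and 69 and 194 without 30 µM 24 h replicates A1 and B2 and 221 without 45 µM 24 h replicate B1. In batch B alone TXNIP (adjusted p = 0.145), MT-RNR1 (0.218), TGM1 (0.0659), SKIDA1 (0.071) and MT-CO2 (0.0931) did not pass. Ferroptosis genes passed with the block (adjusted p = 0.0485, estimated 0.295) and not without it (0.053).

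At 48 h 103 genes were higher and 301 lower at 45 µM than at 30 µM. Genes of G2 and mitosis were lower in 20 of 26 cases and 24 over the list alone, with PLK1 at -0.78 ± 0.09 and AURKA at -0.67 ± 0.08 (adjusted p = 6.76e-60, estimated 0.147). Type I interferon genes were lower at 45 µM in 6 of 29 cases and 12 over the list alone, with OAS1 at -0.97 ± 0.17 and IFI44 at -0.94 ± 0.19 (median log2 -0.35, adjusted p = 2.03e-10, estimated 0.32). The largest falls by the rule were IFIT1 (-1.74 ± 0.35), IFITM1 (-1.56 ± 0.34) and the helicase gene PIF1 (-1.35 ± 0.19). Of the ovarian carcinoma markers 6 of 18 were lower, and 7 lower and 3 higher over the list alone, with KRT19 at -0.37 ± 0.06 (adjusted p = 0.00495, estimated 0.32). Rises were smaller, with GOLGA7B at 0.95 ± 0.24, VGLL3 at 0.83 ± 0.20, PCLO at 0.79 ± 0.13 and CEBPG at 0.26 ± 0.05. The count of 404 was 1543 with the replicate block, 187, 155 and 215 without 30 µM 48 h replicates C1, C2 and C3, and 189 without 45 µM 48 h replicate C3. With the block the lists of hypoxia (adjusted p = 0.0304, against 0.064 without it), complex IV (0.0418, against 0.069), BCL2 family and death receptors (0.0169, against 0.064), immediate early genes (0.0169, against 0.064) and ferroptosis (0.0119, against 0.0776) passed as well. With an estimated correlation none of these 5 did (0.38, 0.38, 0.28, 0.38 and 0.28).

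Whether the response changed between 8 and 24 h was tested as an interaction within the fit of batches A and B. For 30 µM edgeR called 0 genes, with 331 at an unadjusted p under 0.05 and 0 by DESeq2. For 45 µM 18 genes had a higher and 34 a lower response at 24 h than at 8 h. The NRF2 genes SRXN1 and OSGIN1 were among the first, with differences in log2 fold change of 1.21 ± 0.15 and 1.37 ± 0.25. As a list 3 of 27 NRF2 targets had a higher response and 12 over the list alone (adjusted p = 7.8e-12, estimated 0.0825). G2 and mitosis genes had a lower response in 7 of 26 cases and 24 over the list alone (adjusted p = 4.59e-36, estimated 0.0825), among them KIF20A (-1.15 ± 0.19) and DLGAP5 (-1.09 ± 0.18). Cholesterol synthesis had a lower response in 2 of 24 cases and 19 over the list alone, with INSIG1 at -1.63 ± 0.27 (adjusted p = 7.45e-19, estimated 0.0825). The count of 52 was 56 in batch B alone, 199 with the block and 204 by DESeq2. It was 22 without DMSO 8 h replicate A1, 22 without DMSO 8 h replicate B2, and 27, 18 and 20 without 45 µM 8 h replicates A1, B1 and B2. It was 29 and 11 without DMSO 24 h replicates A1 and B1, and 150, 22 and 98 without 45 µM 24 h replicates A1, B1 and B2. With the block the list calls of glycolysis (adjusted p = 0.0689), hypoxia (0.0582) and ferroptosis (0.0689) ended, and with an estimated correlation 0 lists passed. In batch B alone OSGIN1 (adjusted p = 0.0604), KIF20A (0.0822) and DLGAP5 (0.0679) did not pass.

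The pentose phosphate pathway is named in the title of the series. Only mRNA levels of its genes were measured here, not flux through the pathway or NADPH. By camera its list did not pass against DMSO at any dose and time. At 45 µM its adjusted p was 0.882 at 8 h, 0.949 at 24 h and 0.295 at 48 h. By fry the list was higher at 30 µM and 24 h (adjusted p = 0.0348, against 0.103 by camera). Its median log2 was 0.05 there, with 0 of 13 members past the threshold and 2 higher over the list alone. At 45 µM and 24 h 1 of 13 members rose and 3 fell, and 3 and 3 over the list alone, and at 48 h 2 rose and 8 fell, also over the list alone. TKT, the transketolase gene, fell by 0.28 ± 0.06 and 0.44 ± 0.06 at 48 h, and PGD, which makes NADPH, fell by 0.22 ± 0.05 at 45 µM and 48 h. TALDO1, the transaldolase gene, had a log2 fold change of 0.23 ± 0.09 at 45 µM and 24 h (adjusted p = 0.0621, and 0.0227 with the block) and fell by 0.14 ± 0.05 at 45 µM and 48 h.

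Of the immunogenic cell death genes, 1 of 23 rose and 9 fell at 45 µM and 24 h, and 3 and 9 over the list alone. The median log2 was -0.13 and the mean 0.19, and camera gave a lower direction (adjusted p = 0.00527, estimated 0.0489, or 0.0726 with the block). The members that fell include chaperones and CALR, calreticulin, which dying cells expose on their surface (ENSG00000179218, chromosome 19, 12938578 to 12944489; -0.72 ± 0.15), and HMGB1, a nuclear protein released by dying cells (-0.60 ± 0.07). At 48 h 7 of 21 rose and 10 fell at 30 µM and 7 rose and 13 fell at 45 µM, also over the list alone, the medians were -0.16 and -0.30, the means 0.30 and 0.25, and the list did not pass (adjusted p = 0.21 and 0.0525). CALR fell by 0.51 ± 0.06 and 0.72 ± 0.06, HMGB1 by 0.53 ± 0.07 and 0.91 ± 0.08 and ANXA1, an eat-me signal of dying cells, by 0.47 ± 0.10 and 0.74 ± 0.10, while the cytokine members IL6, TNF and CXCL10 rose, as given above. These are mRNA levels, and exposure or release of the proteins was not measured here. HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.56 ± 0.17 at 45 µM and 24 h and fell by 0.38 ± 0.05 and 0.29 ± 0.05 at 48 h. DHODH, the mitochondrial enzyme of pyrimidine synthesis, had log2 fold changes of 0.28 ± 0.17 at 45 µM and 24 h (adjusted p = 0.269) and -0.04 ± 0.14 at 48 h (adjusted p = 0.841).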

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

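The exchanges of time labels, the histone test of the mitochondrial pattern, and the fit of batch B with the replicate block were chosen only after the results were seen. The first values below drew attention because the effect of the same dose differed between 8 and 24 h in a test of the difference itself. At 45 µM this held for 52 genes and 19 gene lists, and at 30 µM for 10 lists and 0 genes in edgeR (331 at an unadjusted p under 0.05, and 0 by DESeq2). With an estimated correlation 0 of these lists passed at either dose. The 52 genes were 61 with median-of-ratios size factors, 56 in batch B alone (16 of them shared) and 199 with the replicate block. They were 865 in batch B with the block, 204 by DESeq2 and 556 without a filter. No gene passed without the batch term or with only the compared groups in the fit (0 in edgeR for each). Without 1 library, the count was 22 (DMSO 8 h replicate A1), 22 (DMSO 8 h B2), 27, 18 and 20 (45 µM 8 h A1, B1 and B2). It was 29 and 11 (DMSO 24 h A1 and B1), and 150, 22 and 98 (45 µM 24 h A1, B1 and B2).

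When the 8 h and 24 h labels were exchanged at random within the 45 µM and within the DMSO libraries, without regard to batch or replicate, 8 of 100 draws, the real labels included, called as many genes as the 52. The highest other draw called 714. When they were exchanged only within each replicate, 8 of 32 splits called as many as the 52, and the highest other called 1558. With the replicate block in the fit, 9 of 32 such splits called as many as the 199, and the highest other called 2738. Chance is therefore not excluded by these tests at 45 µM. In each of the 7 other draws, the 45 µM libraries of each time stayed together while the DMSO libraries of both times were mixed. In all but 1 of the other splits within replicates that called as many, DMSO labels alone were exchanged. The change of the cultures with time was then not subtracted as in the real labels, which is a structure of the samples. The remaining split followed the batch, with the 45 µM labels exchanged in batch B and not in batch A, and called 76 genes (392 with the block), against 52 (199) under the real labels in the same fit. The fit of batch B alone, whose counts are not comparable with these, called 56 (865 with the block) under the real labels. For 30 µM the real labels called 0 genes, which every split matches, so that 100 of 100 draws and 32 of 32 splits within replicates, without and with the block, say nothing about chance. The highest others called 148, 785 and 1803.

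The genes named by the rule had these differences in log2 fold change between 24 and 8 h at 45 µM. Higher at 24 h were SYNE3 by 2.08 ± 0.42 (adjusted p = 0.0351; 0.21 at 8 h and 2.30 at 24 h), UPP1 by 1.83 ± 0.31 (0.011; 0.98 and 2.80), OSGIN1 by 1.37 ± 0.25 (0.0186; 0.58 and 1.95). So were SLC22A15 by 1.36 ± 0.29 (0.0386; 0.34 and 1.70) and SRXN1 by 1.21 ± 0.15 (0.000613; 0.24 and 1.45). Lower at 24 h were LIX1 at -2.08 ± 0.36 (0.011; -0.01 and -2.10), METTL7A at -1.88 ± 0.40 (0.0386; -0.30 and -2.17), INSIG1 at -1.63 ± 0.27 (0.0106; -0.11 and -1.74). So were KIF20A at -1.15 ± 0.19 (0.00803; -0.54 and -1.70) and NR2F1 at -1.11 ± 0.20 (0.0183; -0.05 and -1.16). LIX1 averaged 0.004 CPM in batch A, so that its value rests on batch B. UPP1, SRXN1, INSIG1 and KIF20A passed whichever library was left out. LIX1 was lost without 45 µM 8 h B2, DMSO 24 h A1, DMSO 24 h B1 or 45 µM 24 h B1. OSGIN1 was lost without DMSO 8 h B2, 45 µM 8 h A1, 45 µM 8 h B2, DMSO 24 h B1 or 45 µM 24 h B1. SYNE3 passed only without DMSO 8 h A1, 45 µM 24 h B1 or 45 µM 24 h B2. SLC22A15 passed only without DMSO 8 h B1 or DMSO 24 h B2, and METTL7A only without DMSO 8 h B1, DMSO 24 h A1 or 45 µM 24 h B2. NR2F1 was lost without DMSO 8 h A1, 45 µM 8 h A1 or DMSO 24 h B1. Not called in batch B alone were SYNE3, OSGIN1, SLC22A15, METTL7A, KIF20A and NR2F1. No explanation of these differences was tested beyond the exchange of labels, and the design names only dose and time.

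The 9 treated and vehicle libraries of batch A stood apart from those of batches B and C. Sequencing depth is argued against, since the correlation of the 24 h DMSO libraries of A and B was 0.849 before and 0.849 after thinning to 20963381 counts each (0.993 within batch B). So are GC content and length, which explained a share of 0.004 of the variance of the ratio across genes, and another RNA selection, since the 40 histone genes had a median log2 ratio of -0.62. What stays open is that RNA of another cell line or population may be in batch A, since 316 protein-coding genes averaged at least 10 CPM in A and under 0.2 in B, or the reverse (98 in A and 218 in B). Whether it is the second line named in the growth protocol was not tested, and no biological explanation was tested. A mixture with a sizeable share of cells like those of batch B is argued against by the 218 genes. Of these, UBB and CDKN2A, named after their values were seen, reached at most 0.399 and 0.317 CPM in the libraries of batch A. In batch B they stood at 384 and 309 or more. A wrong label was not told apart from a mixture of other cells.

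At 45 µM and 24 h the mitochondrial rRNAs, named after their values were seen, rose, MT-RNR1 by 1.61 ± 0.37 (adjusted p = 0.0042) and MT-RNR2 by 1.18 ± 0.33 (0.0163), while 9 of 13 mitochondrially encoded mRNAs fell and 1, MT-ND1, rose by 0.38 ± 0.12. A single deviating 45 µM library is argued against, since the mean log2 fold change of both rRNAs, 1.40 with all libraries, was 1.35, 1.27 and 1.54 without replicates A1, B1 and B2. At 45 µM and 8 h MT-RNR1 stood at 1.22 ± 0.37 (adjusted p = 0.159) and MT-RNR2 at 0.42 ± 0.33 (0.8), with their joint share of the counts above that of DMSO in all 3 pairs, while at 48 h, in batch C, they stood at -0.69 ± 0.18 (0.0263) and -0.21 ± 0.08 (0.07) at 30 µM and at -0.31 ± 0.18 (0.212) and -0.42 ± 0.08 (0.00148) at 45 µM. Weaker selection of polyadenylated RNA may raise the rRNAs and cannot be told apart from an effect of the drug, since nuclear small RNAs without a poly(A) tail had a median of -0.27, under the bound set beforehand, but only 3 were tested, with 0 higher and 0 lower, too few to decide. Histone mRNAs had a median of -0.62 (0 of 40 higher and 8 lower), but genes of S phase fell as well (median -0.41), so that less DNA replication could hide a rise, and the dose, which the design names, stays open as the biological explanation.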

How the results depend on the processing

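Batch B alone with the replicate block, the block in list tests, and the other treatments of the repeated untreated library were chosen only after the data were seen. Unless said otherwise, the cause of a difference was not tested. With median-of-ratios size factors, every count of genes called stayed within 1.5-fold, and of the named genes 768 calls were unchanged, 2 were lost and 1 was gained. The counts at 48 h against DMSO also stayed within that range under every alternative run for them. They went from 5075 (DESeq2) to 6715 (replicate block) at 30 µM and from 6709 to 8236 at 45 µM, and the single libraries left out are given below.

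With the replicate block, the counts of genes called rose to 3 at 30 µM and 8 h, 352 at 45 µM and 8 h, and 222 at 30 µM and 24 h. They rose to 1108 and 1543 for 45 µM against 30 µM at 24 and 48 h, 445 for DMSO at 24 against 1 h, and 199 for the response at 45 µM. The block changed no other count by more than 1.5-fold. Of the named genes 739 calls were unchanged, 31 were gained and 1 was lost. Of the list calls 214 of 224 were kept and 10 lost. Lists called in untreated against DMSO went from 1 to 5.

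In batch B alone, with fewer libraries, the counts were 6 at 30 µM and 8 h, 258 at 45 µM and 8 h, and 211 at 30 µM and 24 h. They were 209 for 45 against 30 µM at 24 h and 103 for DMSO at 24 against 1 h (75 shared with both batches). Of the named genes 475 calls were unchanged, 53 lost and 11 gained. With the block as well, the first 3 were 102, 991 and 1172, and 45 µM at 24 h had 5536. The block gave 62 and 1484 for 45 against 30 µM at 8 and 24 h, 471 for DMSO at 24 against 1 h, and 1 and 865 for the responses at 30 and 45 µM. Then 489 named calls were unchanged, 12 lost and 38 gained. Lists called in batch B alone were 4 at 30 µM and 1 h, 4 for untreated and 6 for DMSO at 24 against 1 h. With the block they were 4, 6 and 8, and 8 at 45 µM and 1 h. Directions reversed for lists of DMSO at 24 against 1 h, without and with the block: pyrimidine synthesis (adjusted p = 0.74 and 0.778), S phase (0.0616 and 0.0456) and mitochondrial ribosomal proteins (0.66 and 0.702). The p53 targets reversed in the response at 45 µM with the block (0.919).

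DESeq2 called 2, 1 and 1 genes at 1 h (30 µM, 45 µM, and 45 against 30 µM), and 10, 326 and 1 at 8 h. It called 210 at 30 µM and 964 for 45 against 30 µM at 24 h, 2 for untreated, 404 for DMSO at 24 against 1 h and 204 for the response at 45 µM. Of the named calls 740 were unchanged, 1 was lost and 28 were gained. Without a filter, 35146 genes were tested in place of 18336, and 30518 in place of 16346 at 48 h. The counts were then 25, 34 and 28 at 1 h, 133, 503 and 150 at 8 h, and 556 at 30 µM and 1049 for 45 against 30 µM at 24 h. They were 939 for 45 against 30 µM at 48 h, 41 for untreated, 684 for DMSO at 24 against 1 h, and 99 and 556 for the responses. Then 669 named calls were unchanged, 8 were lost and 94 gained. Of the 152 genes of 45 µM at 8 h, 121 were among the 503.

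Without the batch term, 4 genes were called at 45 µM and 8 h, and 0 at 30 µM and 198 at 45 µM at 24 h. There were 3 for 45 against 30 µM at 24 h, 6 for DMSO at 24 against 1 h and 0 for the response at 45 µM, and 363 named calls were unchanged and 177 lost. By construction, the difference between batches A and B then counts as spread. With only the compared groups in the fit, hence fewer libraries to estimate the spread, the counts were 11 at 45 µM and 8 h, and 12 and 1595 at 30 and 45 µM at 24 h. They were 1 and 31 for 45 against 30 µM at 8 and 24 h, 34 for DMSO at 24 against 1 h and 0 for the response at 45 µM. Here 654 named calls were unchanged, 113 lost and 3 gained. The repeated untreated library gave 4211 genes entered as batch A, where PGD (0.99) and UQCRC1 (1.32) reversed on the log2 scale, and 358 counted as 2 libraries.

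With an estimated correlation, lists called fell to 0 and 0 at 1 h, 1, 1 and 1 at 8 h (30 µM, 45 µM, and 45 against 30 µM), 2, 5 and 4 at 24 h, and 8, 4 and 0 at 48 h. They fell to 0 for untreated, 2 for DMSO at 24 against 1 h and 0 for both responses. By fry they were 0 and 0 at 1 h, 0, 5 and 0 at 8 h, 9 at 30 µM and 13 for 45 against 30 µM at 24 h, and 9 for 45 against 30 µM at 48 h. They were 0 for untreated, 4 for DMSO at 24 against 1 h, and 0 and 7 for the responses.

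Each library was left out in turn, and where this left 1 library of a batch in an arm, that library was assumed to vary like the other groups. The counts, lowest to highest, were 0 to 0 at 30 µM and 0 to 1 at 45 µM at 1 h, and 0 to 0 and 40 to 110 at 8 h. They were 11 to 110 and 2343 to 3296 at 24 h, and 4384 to 5127 and 6287 to 6739 at 48 h. For 45 against 30 µM they were 0 to 0 at 1 and 8 h, 69 to 608 at 24 h and 155 to 530 at 48 h. For untreated they were 0 to 0, for DMSO at 24 against 1 h 64 to 141, and for the responses 0 to 0 and 11 to 150. Of the named gene calls 4591 were unchanged, 421 lost and 17 gained. Depth limits what was tested at low counts, since with 15580526 to 40512449 counts per library 18336 of 63140 genes passed the filter in the first fit and 16346 in that of 48 h.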

Other observations

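All counts over splits of the libraries in this part were chosen only after the results were seen, and the genes named here were chosen after their values were seen. The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. At 1, 8 and 24 h the replicate names pair the libraries. Then 3 of the other splits part all pairs as the real one does, and the rest put both libraries of a pair on the same side. For 45 µM against DMSO at 8 h the real split called 152 genes and was 1 of 10 to call as many. The highest other called 13, and the highest of those that part all pairs 6. These values were 61, 1 of 10, 6 and 6 for 30 µM at 24 h, and 3436, 1 of 10, 195 and 195 for 45 µM at 24 h. They were 209, 1 of 10, 0 and 0 for DMSO at 24 h against 1 h. For 45 µM against 30 µM at 24 h they were 530, 1 of 10, 323 and 4. The split with 323 put both batch A libraries and 30 µM replicate B2 on the same side. At 48 h the real split called 5584 genes at 30 µM and 7293 at 45 µM, with 0 as the highest other for each. It called 404 for 45 µM against 30 µM, with 1 as the highest other and 0 among those that part all pairs, and in all 3 it was 1 of 10. In the comparisons in which edgeR called 0 genes, at 1 h for both doses and between them, and at 8 h for 30 µM and between the doses, 10 of 10 splits called as many and the highest other was 0.

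The untreated libraries titled batch A replicate 1 and batch B replicate 1 held the same value at every gene. The series therefore has no untreated library with the profile of batch A. GATA3 averaged 153 ± 47.0 CPM in batch A (SD, n = 9), 0.00504 ± 0.0154 in batch B (SD, n = 18) and 0.0191 ± 0.0288 in batch C (SD, n = 9). UBB averaged 0.193 ± 0.132, 465 ± 33.5 and 500 ± 52.5 in the same batches, and PAX8 52.9 ± 9.03, 664 ± 106 and 448 ± 72.8.

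Of the 110 genes higher at 45 µM and 8 h that were tested in both fits, 103 were also higher at 45 µM and 48 h, where chance gives 24.7. Of the 42 lower genes 34 were also lower, where chance gives 9.5, and 1 was higher. The DMSO libraries of 8 h and 48 h are different libraries.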
